A study of Homo sapiens with 4 samples.

How the data were processed

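The data are expression profiles of the leukemia line SKNO-1 on 4 Illumina BeadChip arrays, 1 per sample, in 1 color. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns with DNase I treatment, checked on a Bioanalyser, and turned into biotin-labelled cRNA with an Ambion MessageAmp kit. Per the file headers, the deposited non-normalized table gives for each probe and array the summary signal, an intensity on a linear scale averaged over the beads of the probe, with no background subtracted as far as the values show. The same deposited table gives a detection p-value from the negative control beads, the standard error over beads as an intensity, and the count of beads behind each signal. The authors also deposited a normalized intensity per probe and array on a linear scale, not log2, whose method is not given in the sources used here. On the log scale it correlated with the summary signal of the same array at 0.9988 or more, and its medians were 121, 120, 117 and 117 for control 1, the array labelled AML1-ETO knockdown, control 2 and the array labelled EZH1 knockdown, against medians of 106, 103, 115 and 118 for the summary signal. The export software, scanner settings and genome build of the probe coordinates are not given in the sources used here.

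Signals were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits a normal plus exponential model using the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Probes with a detection p under 0.01 on at least 1 array were kept (16946 of 47323, control probes left out), and the share of probes detected was 28.7, 28.6, 32.0 and 32.5% in the order above. Gene symbols were updated through the Entrez number of each probe with a table of RefSeq genes of the GRCh38.p14 assembly, used for names only; 35672 probes matched and 11651 kept the name in the file. For the 2888 genes with more than 1 kept probe, the probe with the highest mean was used, which left 13369 genes, and the other probes of named genes are reported where they exist. Where all arrays of a group were below background, a fold is given as a bound: the mean of the detected side against the higher of the measured value and the lowest detected value of each array on the other side, on normalized log2 values. Each bound is thus against the mean of both controls and can be smaller against 1 control alone. Bead errors were carried to the log2 scale from the background-corrected signal.

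Groups came from the sample titles. The tests, the 38 gene lists and the rule for named genes were fixed before the data were examined. Genes were tested with limma's lmFit and eBayes on 3 group means over all 4 arrays with Benjamini-Hochberg adjustment at 0.05. The controls are the 1 replicated group, so the fit had 1 residual degree of freedom (prior 7.14) and assumed that a knockdown array varies like the controls; the median standard error of a knockdown difference was 0.53. The p-values measure the spread between these arrays only. The controls lay further apart than either lay from 1 of the knockdown arrays, so that assumption is in doubt. The error is likely too large for the difference of a knockdown array from its nearer control, and a lack of passing genes does not show a lack of change. Genes at least 2-fold from both controls were counted without a test. The median difference of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. Correlations of fold changes were set beside 100 simulations of unchanged arrays, in which the controls were also drawn anew around each gene's control mean. After the data were seen, 100 simulations each were added with 1 shared control and with arrays that differ by pair, the latter with a spread within pairs of 0.24 taken from the observed pairs, any knockdown effect included. The named genes are RUNX1, RUNX1T1 and EZH1, then for each knockdown the 12 highest and 12 lowest that passed limma on the same side of both controls, filled, where fewer passed, with those having the largest difference from the nearer control; all 24 were filled in this way in both comparisons. For each list described, up to 4 detected members with the largest difference from the control mean are named, and loci without a gene name are counted but not named. Some genes that these rules select are not reported here. Genes named for the difference between the controls were chosen after its values were seen.

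The limma step, whose recovery on arrays that differ by pair was not simulated, was tested on simulated data without array pairs for the AML1-ETO comparison: 20 runs on 13369 genes with 200 changed genes each. It recovered 4.6% of genes changed 2-fold, 55.7% changed 4-fold, 97% changed 8-fold and 99.9% changed 16-fold, with a mean of 16.4 false calls, and made a mean of 2.2 calls where nothing had changed. Alternatives were no background correction, scaling to the 75th percentile in place of quantiles, the authors' values, all probes or only those detected on all 4 arrays, the mean of a gene's probes, eBayes with trend and robust options, an adjusted p of 0.1, a fold of 1.5, fits with 1 knockdown or with both as 1 group, and each control left out. Raising values to the detection floor and a fit with the array pairs as a block were added after the data were seen. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.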

Results

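Transcript levels were measured in SKNO-1, a human myeloid leukemia cell line that carries the t(8;21) translocation and its fusion protein AML1-ETO (RUNX1-RUNX1T1). The 4 samples form 3 groups: 2 scrambled controls, 1 knockdown of AML1-ETO and 1 knockdown of EZH1, a histone methyltransferase of Polycomb repressive complex 2 (PRC2). Total RNA of each was hybridized to an Illumina expression BeadChip, an array on which each probe is read from many beads. Of 47323 probes, 13578 were above background on control 1, 13515 on the array labelled AML1-ETO knockdown, 15126 on control 2 and 15350 on the array labelled EZH1 knockdown. The median number of beads per probe was 20, 20, 22 and 21 in that order, and the median standard error over beads of detected probes was 4.55, 4.24, 4.13 and 4.08% of the signal. The 92 spike-in control probes gave 0 detections on each array. The number of arrays limits the precision: each knockdown has 1 array, so no value of a knockdown has a replicate error, and the labels do not say whether the controls came from separate cultures. Errors over beads cover measuring error within an array only. Differences are on the log2 scale unless a fold is given.

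The targeted genes were examined on each array. RUNX1T1, which supplies nearly the whole ETO part of the fusion, was detected by 1 of its 5 probes, at transcript position 2988 (chromosome 8, 93041171 to 93041220, genome build not given in the sources used here), which reads the fusion and RUNX1T1 alike. Its signal was 397 ± 21.6 (standard error over beads) on control 1, 443 ± 24.6 on the array labelled AML1-ETO knockdown, 633 ± 44.8 on control 2 and 648 ± 31.4 on the array labelled EZH1 knockdown. The normalized value on the array labelled AML1-ETO knockdown was 0.18 above control 1 (bead error 0.14) and 0.47 below control 2 (difference -0.47), so the label was not borne out against control 1. That array is therefore called the AML1-ETO-labelled array throughout, and each direction given for it rests on the label alone. RUNX1 was detected on all arrays by a probe at transcript position 5885 (chromosome 21, 35082209 to 35082258), which lies in the part of RUNX1 that the fusion lacks and so checks nothing about the fusion. It differed by -0.29 from control 1 and by -0.075 from control 2 on the AML1-ETO-labelled array. A further RUNX1 probe was above background only on control 2 and the EZH1-labelled array, which differed by 0.0058 there. EZH1 was close to background: its only probe (chromosome 17, 38105896 to 38105945) read 108 ± 5.49 and 145 ± 9.03 on the controls, 112 ± 6.79 on the AML1-ETO-labelled array and 137 ± 10.9 on the EZH1-labelled array, and was detected on control 2 alone. The EZH1-labelled array differed by -0.41 from control 2 (bead error 0.44) and by 0.48 from control 1, so a lower EZH1 level was not detectable with this probe.

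**Figure D1:**
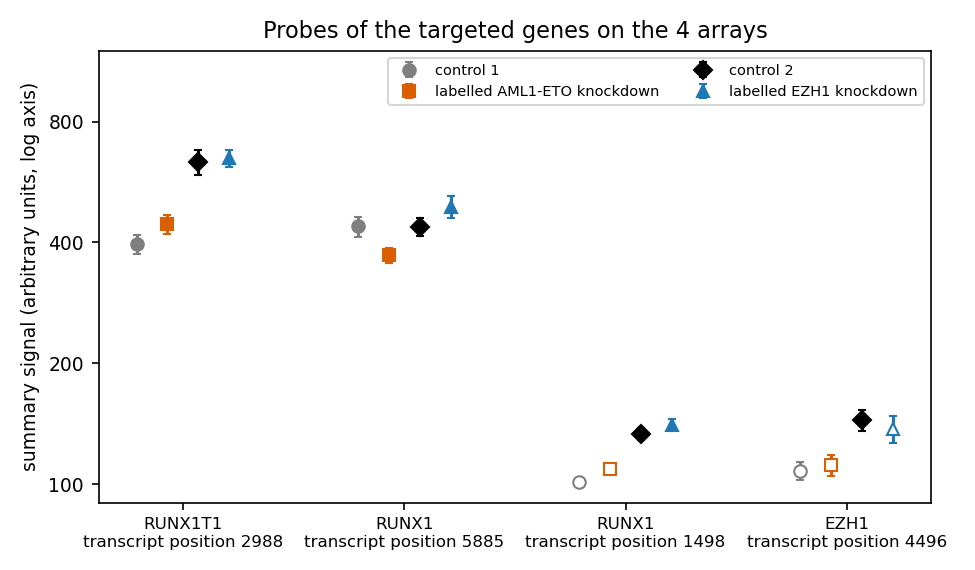
Summary signal (arbitrary units, log axis) of the detected probes of RUNX1T1, RUNX1 and EZH1 on the 4 arrays, with 1 symbol per array, bars for the standard error over beads and open symbols where the probe was not above background. The RUNX1T1 probe read 397 on control 1 and 443 on the AML1-ETO-labelled array, and the EZH1 probe was detected on control 2 only.

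The controls differed from each other more than each did from 1 of the knockdown arrays. Amino acid response genes such as ASNS, which encodes asparagine synthetase, and DDIT3, a stress-induced transcription factor, were higher on control 2 (2.61 and 2.65), whereas RRM2, a subunit of ribonucleotide reductase, was lower there (-2.24). In all, 1189 genes were at least 2-fold higher and 850 at least 2-fold lower on control 2 than on control 1, and 1969 of these 2039 differed by more than 3 bead errors. The AML1-ETO-labelled array lay near control 1 (257 genes apart by 2-fold, correlation across genes 0.985) and far from control 2 (1441 genes, 0.955), and the EZH1-labelled array lay near control 2 (49 genes, 0.990) and far from control 1 (2307 genes, 0.938). The sample numbers in the labels also set control 1 beside the AML1-ETO-labelled array and control 2 beside the EZH1-labelled array, but no label states a shared batch. Values against each control are therefore given side by side, except the fold bounds, which are against the mean of both controls. The control nearer in this sense is the closest to a comparison within a batch. The limma fits below take their error from this difference of the controls, so a lack of passing genes does not show that nothing changed.

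The first comparison asked which transcripts differ after knockdown of AML1-ETO. The AML1-ETO-labelled array read higher than both controls for neutrophil granule genes as a list and for PRG2 and RNASE2, and lower for MHC class II molecules. PRG2, the major basic protein of eosinophil granules, was 1.37 above control 1 and 3.05 above control 2, and RNASE2, the eosinophil-derived neurotoxin, was 1.34 and 2.12 above them. SLC40A1, the iron exporter ferroportin, was not above background on either control and was at least 2.91-fold higher on the AML1-ETO-labelled array. GNG11, a G protein gamma subunit, was lower by both measures (-2.26 and -3.22), and HLA-DPA1, an MHC class II chain, was at least 2.06-fold lower than the control mean. In the limma fit 0 of 13369 genes passed at an adjusted p of 0.05, the smallest adjusted p was 1.00, and 38 genes had an unadjusted p under 0.05.

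In that comparison 44 genes were at least 2-fold from both controls, 24 higher and 20 lower, against 109 genes for control 1 measured from its neighbouring array and control 2. Of the 44, 36 exceeded 3 bead errors. Among the 12 named as highest, SLC39A10, a zinc importer, was 1.24 above control 2 and below background on control 1, and ANXA1, a phospholipid-binding protein that dampens inflammation, was 1.13 and 1.28 above them. KIF1A, a kinesin motor, was at least 2.09-fold higher and QTRT1, a subunit of the enzyme that places queuine in transfer RNA, at least 1.96-fold higher. VSTM2B, LRP11, MYRIP, LINGO2 and STAC were likewise below background on both controls, with lower bounds of 1.53-fold, 1.49-fold, 1.45-fold, 1.23-fold and 1.18-fold. Among the 12 named as lowest, TAL1, a basic helix-loop-helix factor of blood stem cells, was at least 2.36-fold lower, PBX3, a cofactor of HOX proteins, at least 2.14-fold lower and YOD1, a deubiquitinase, at least 2.72-fold lower. These bounds are against the control mean, and YOD1 read 6.54 on control 1 and 7.55 on control 2, so less holds for it against control 1. SLFN11, which blocks replication under DNA damage, was at least 1.86-fold lower, and its other probe had a fitted difference of -0.54 from the control mean against -1.98 for the probe used. SCARNA11, a small Cajal body RNA, HLA-DRB6, an MHC class II pseudogene that can share signal with its relatives, and GUCY1B1, a subunit of soluble guanylate cyclase, had bounds of 1.71-fold, 1.98-fold and 1.07-fold lower. MIR1974 differed by -1.33 and -1.43, DBNDD2 by -1.11 and -3.04, and RNA28SN5, a copy of the large-subunit ribosomal RNA, by -1.13 and -4.61, with a fitted difference of -2.87 against -1.74 for its other probe. With values raised to each array's lowest detected value, 17 genes passed 2-fold from both controls, and 5 passed without background correction as well as in the authors' own normalized values. Against control 1 alone the count was 257 and against control 2 alone 1441.

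**Figure D2:**
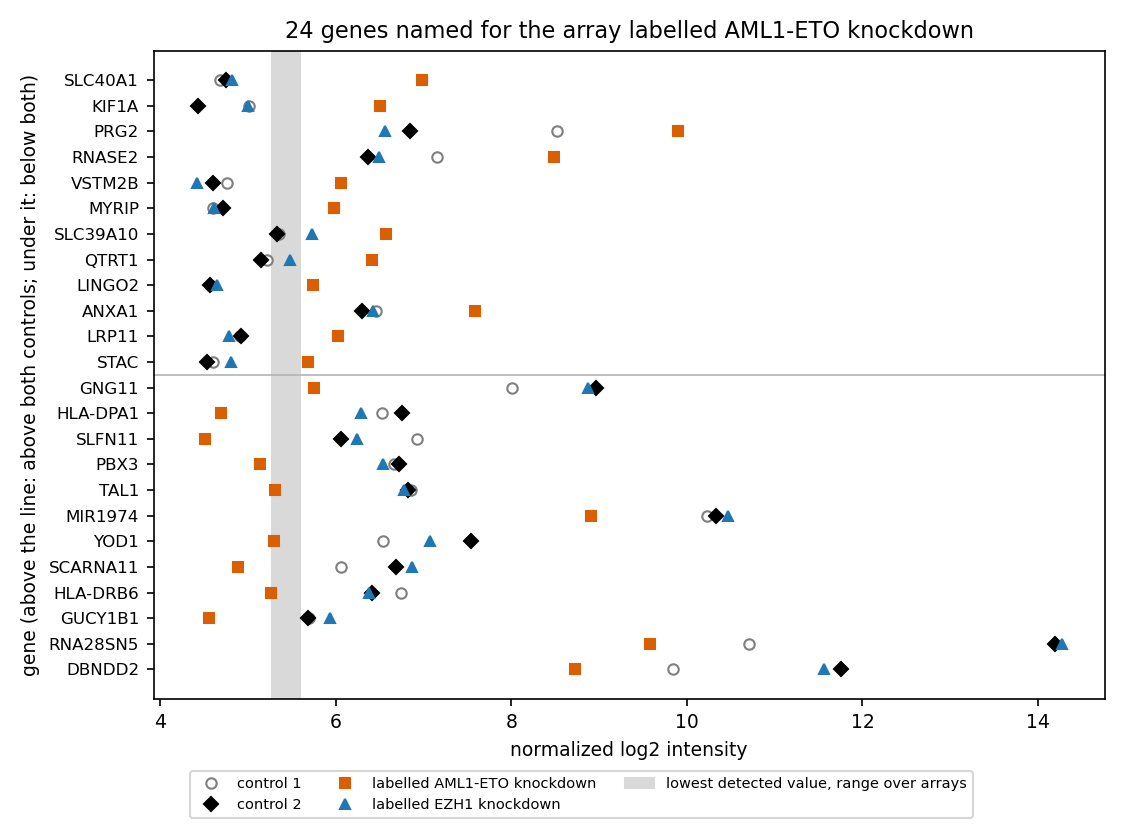
Normalized log2 intensity of the 24 genes named for the AML1-ETO-labelled array, with 1 symbol per array and a grey band for the range over arrays of the lowest detected value. PRG2 reads 9.90 on the AML1-ETO-labelled array against 8.53 and 6.85 on the controls, and GNG11 reads 5.75 against 8.01 and 8.97.

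Blood lineage lists moved in different directions on the AML1-ETO-labelled array. The median of 12 detected primary granule and neutrophil genes was 0.18 above control 1 and 0.35 above control 2 (percentiles 97.5 and 97.7 among 10000 matched random lists), with 7 members above both controls and 0 below both. Beside RNASE2, ELANE, which encodes neutrophil elastase, was 0.31 and 2.10 above the controls, and AZU1 and CTSG, which encode further azurophil granule proteins, were 0.15 and 0.53, and 0.26 and 0.37, above them. The 6 detected MHC class II genes had medians of -0.76 (percentile 0, below all random lists) and -1.31 (percentile 0.01), and 5 of them were below both controls. HLA-DPA1 was the 1 member that passed when the limma p was adjusted over the list alone (adjusted p = 0.031), but it was not above background on the AML1-ETO-labelled array, so that p rests on an undetected value and only the bound of 2.06-fold holds. That bound is against the control mean, and HLA-DPA1 read 6.53 on control 1 and 6.76 on control 2. HLA-DRA differed by -0.94 and -1.53, HLA-DMA by -0.58 and -1.87, and HLA-DRB4, whose probe may not separate it from related genes, by -1.03 and -0.67. The 7 detected mast cell, eosinophil and basophil genes had medians of -0.023 and -0.30 (percentiles 43.8 and 15.7), with 2 members above both controls, PRG2 and the mast cell carboxypeptidase gene CPA3 (0.68 and 1.11), and 3 below both, among them FCER1A, a chain of the IgE receptor (-0.32 and -0.85). In monocyte and macrophage genes the medians were 0.15 and 0.14 (percentiles 91.8 and 84.2), where TYROBP, a signaling adaptor, was 0.86 and 0.77 above the controls and FCGR1A, an immunoglobulin receptor, differed by -0.96 and -1.95. The 15 detected stem and progenitor genes had medians of -0.081 (percentile 16.9) and -0.45 (percentile 0.79), with 8 members below both controls and 0 above both. Among these, ANGPT1, a ligand that supports stem cells, differed by -0.98 and -1.28, and SPINK2 was at least 1.19-fold lower.

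Genes that AML1-ETO is known to regulate were divided by the direction of that regulation. The 14 detected genes listed as activated by AML1-ETO had medians of -0.27 (percentile 0.01) and -0.51 (percentile 0.32), with 7 members below both controls and 2 above both. POU4F1, a homeodomain factor typical of leukemia with this fusion, differed by -0.79 and -2.18, and SIPA1L2 by -0.46 and -1.12. In contrast, ID1 differed by -0.47 and 2.21, so its direction depended on the control. CAV1, the coat protein of caveolae, was detected on control 2 but neither on control 1 nor on the AML1-ETO-labelled array. The 23 detected genes listed as repressed by AML1-ETO had medians of 0.13 (percentile 96.6) and 0.20 (percentile 93.5), inside the central 95% of random lists, with 9 members above both controls and 5 below both. This list shares RNASE2, ELANE and other granule genes with the list above. LAT2, an adaptor of immune receptors, was 0.44 and 1.02 above the controls and RASSF2, a RAS effector, was 0.42 and 0.83 above them. With undetected probes kept, the median of the activated list against the control mean was -0.085 (percentile 5.26) and that of the granule list 0.060 (percentile 92.5).

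Some metabolic and proliferation lists lay on the same side of both controls, and others depended on the control. The 30 oxidative phosphorylation genes had medians of 0.090 (percentile 97.9) and 0.36 (percentile 100), with 18 above both controls and 2 below both. SDHA, a subunit of succinate dehydrogenase, was 0.73 and 0.99 above the controls. The 17 detected endoplasmic reticulum chaperone genes had medians of 0.27 (percentile 99.99) and 0.35 (percentile 98.9), where HSP90B1 was 0.69 above both controls, HSPA5 0.27 and 1.58, and MANF 0.28 and 1.35, and DNAJC3 was at least 1.21-fold higher. In contrast, hypoxia and HIF target genes had a median of 0.96 against control 1 and -0.094 against control 2 (percentiles 100 and 35.3). BNIP3, a mitophagy receptor, differed by 1.96 and -0.13 and DDIT4, an inhibitor of mTORC1 signaling, by 2.62 and -0.78, whereas SLC2A1, the glucose transporter GLUT1, was 0.97 and 1.19 above the controls. The glycolysis list gave 0.23 and 0.11 (percentiles 99.99 and 84.7), with 13 of 20 members above both controls, although the controls differed by only 0.0055. G2 and mitosis genes gave 0.10 and 0.42 (percentiles 95.3 and 99.96), with 13 of 28 members above both controls and 2 below both. Cholesterol synthesis genes gave 0.083 and 1.11 (percentiles 87.5 and 100), and HMGCS1, an early enzyme of the pathway, was 0.52 and 2.43 above the controls. S phase genes gave -0.29 and 0.76 (percentiles 0 and 100), and RRM2 differed by -0.41 and 1.83. Between the controls themselves the hypoxia, cholesterol and S phase medians differed by 1.04, -1.18 and -0.96 (control 2 minus control 1). Markers of other cell types were few: 4 of 20 T and NK lymphocyte genes on the array were detected, 4 of 15 B lymphocyte genes and 2 of 18 fibroblast and epithelial genes, with medians of 0.50 and -0.35, -0.23 and 0.15, and 0.067 and -1.30 against controls 1 and 2.

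**Figure D3:**
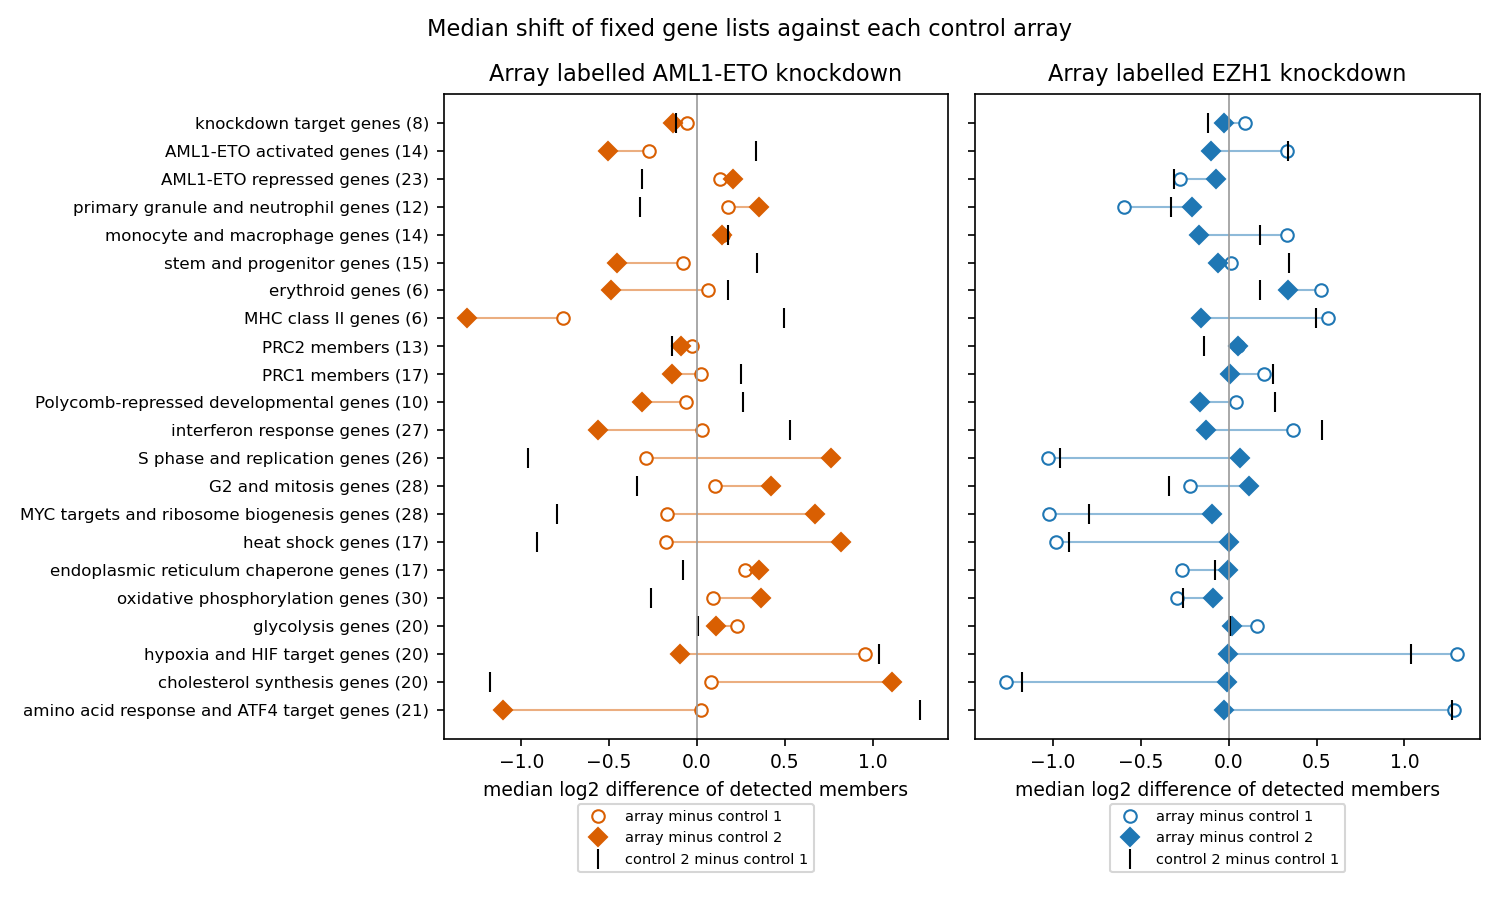
Median log2 difference of the detected members of 22 gene lists (number of members in brackets) on the AML1-ETO-labelled array (left) and the EZH1-labelled array (right), against control 1 (open circles) and control 2 (diamonds), with the difference of the controls as a black tick. MHC class II genes lie at -0.76 and -1.31 on the left, and cholesterol synthesis genes at 0.083 and 1.11.

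The comparison for EZH1 asked which transcripts differ after its knockdown. The EZH1-labelled array read lower than both controls for primary granule genes as a list and higher for RNU4-1 and for the probe of the pseudogene RPL6P10. CTSG, the granule protease cathepsin G, differed by -0.95 from control 1 and by -0.85 from control 2, and ELANE by -2.34 and -0.56. BST2, the antiviral membrane protein tetherin, differed by -1.63 and -1.03. RNU4-1, a U4 spliceosomal RNA, was 3.35 and 1.13 above the controls, and TMEM135, a protein of peroxisomes and mitochondria, 1.49 and 1.03 above them. The rise of RNU4-1 was not particular to this array: it read 8.52 on the AML1-ETO-labelled array, 7.44 on control 1 and 9.66 on control 2. Of 154 ribosomal and small RNA genes, a set chosen after the results were seen, 107 were above control 2 on the EZH1-labelled array and 47 below. The limma fit passed 0 of 13369 genes at an adjusted p of 0.05, with a smallest adjusted p of 1.00 and 17 genes at an unadjusted p under 0.05.

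On the EZH1-labelled array 21 genes were at least 2-fold from both controls, 10 higher and 11 lower, of which 16 exceeded 3 bead errors, against 12 genes for control 2 measured from its neighbouring array and control 1. Among the highest, XRCC2, which acts in recombination repair, was 0.98 and 1.02 above the controls, but its other probe had a fitted difference of -0.39. ZNF679, a zinc finger gene, was 1.01 and 1.33 above them. RPL6P10 and HNRNPA1P35 read 1.23 and 1.06, and 1.12 and 1.01, above the controls, and both are pseudogenes whose probes can share signal with the parent gene, as can RPL10L and IGBP1P1 (at least 1.67-fold and 1.42-fold higher). The other probe of HNRNPA1P35 had a fitted difference of 0.22 against 1.07 for the probe used. CSTPP1, FSTL3, an activin-binding protein, ZNF311 and RDH8, a retinol dehydrogenase, were below background on both controls, with lower bounds of 1.60-fold, 1.54-fold, 1.53-fold and 1.07-fold. Among the lowest, PRKDC, the catalytic subunit of DNA-dependent protein kinase, differed by -1.68 and -1.08, while its 3 other probes had fitted differences of -0.72, -0.19 and 0.56. DPP7, a lysosomal dipeptidyl peptidase, differed by -1.23 and -0.98, and its 3 other probes had fitted differences of -0.51, -0.77 and -0.55. GPKOW differed by -1.06 and -1.18, RER1, a retrieval receptor of the endoplasmic reticulum, by -1.23 and -0.93, B4GAT1, a glycosyltransferase, by -1.09 and -0.94 and the pseudogene RPS2P9 by -1.02 and -0.94. The other probe of B4GAT1 had a fitted difference of 0.49, and the other probes of RER1 and RPS2P9 lay on the lower side. SMPD4, a sphingomyelinase, HAAO of the kynurenine pathway, DIS3L2, an exoribonuclease, and CERKL were at least 1.45-fold, 1.39-fold, 1.36-fold and 1.09-fold lower. With values raised to the lowest detected value 13 genes passed 2-fold, with probes detected on all 4 arrays 11, without background correction 5 and in the authors' values 2. Against control 2 alone the count was 49 and against control 1 alone 2307.

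**Figure D4:**
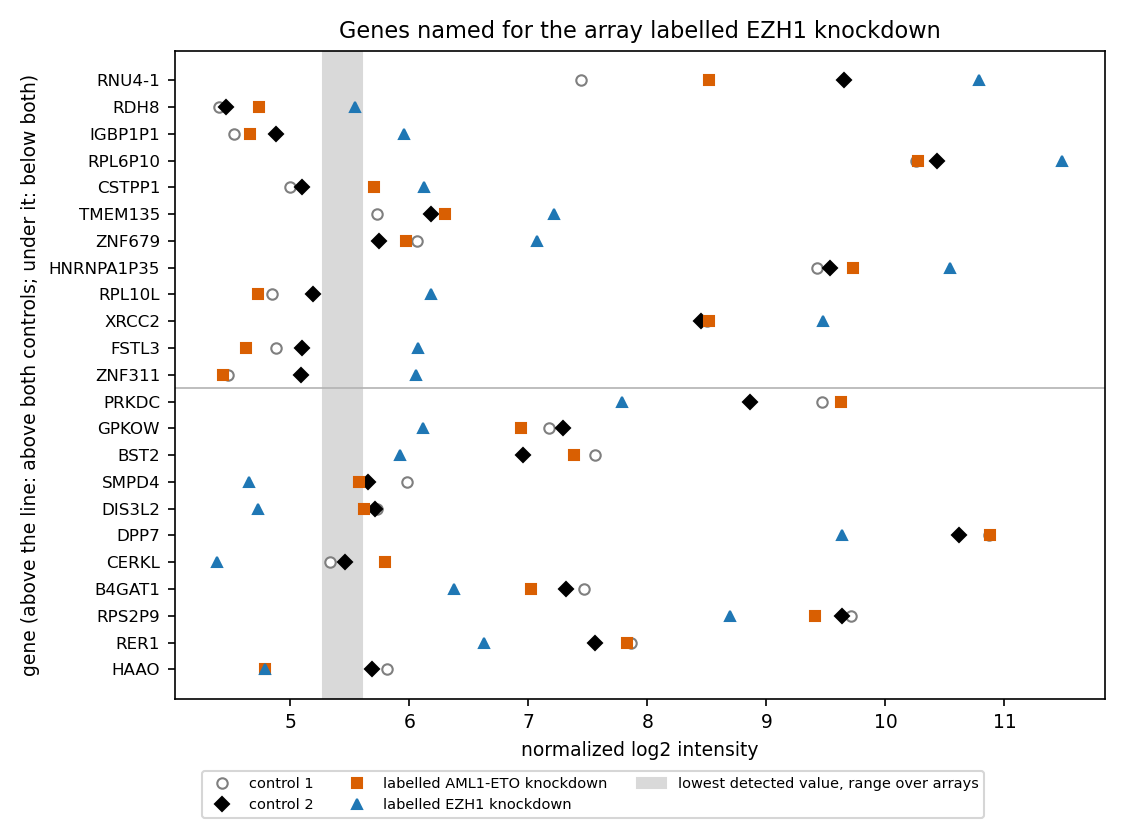
Normalized log2 intensity of the genes named for the EZH1-labelled array, with 1 symbol per array and a grey band for the range over arrays of the lowest detected value. BST2 reads 5.92 on the EZH1-labelled array against 7.56 and 6.95 on the controls, and RNU4-1 reads 10.8 against 7.44 and 9.66.

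Of the gene lists, primary granule and neutrophil genes alone lay outside the central 95% of random lists on the same side against both controls on the EZH1-labelled array. Their median was -0.60 against control 1 and -0.21 against control 2 (percentiles 0.33 and 0.77), with 8 of 12 members below both controls and 1 above both, while in the authors' values the median against the control mean was -0.21 (percentile 3.30). LYZ, lysozyme, differed by -0.32 and -0.55, and FPR1, a formyl peptide receptor, was at least 1.48-fold lower than the control mean. However, FPR1 read 5.45 on control 2, close to the lowest detected value of 5.28 on the EZH1-labelled array. The genes listed as repressed by AML1-ETO had medians of -0.28 and -0.074 (percentiles 6.39 and 17.4), and TNFRSF1B, a tumor necrosis factor receptor, differed by -1.17 and -0.54. The 6 detected erythroid genes had medians of 0.53 and 0.34 (percentiles 94.6 and 99.3), where HBB, beta globin, was 0.43 and 0.63 above the controls and HBA2, whose probe may also read its copy HBA1, 0.62 and 0.44. With undetected probes kept, the erythroid median against the control mean was -0.0092. PRC2 members had medians of 0.052 and 0.055 (percentiles 52.8 and 78.0), and EED and JARID2, a core and an accessory subunit, were 0.38 and 0.85, and 1.01 and 0.37, above the controls. PRC1 members had medians of 0.20 and 0.0080 (percentiles 78.1 and 57.4), with CBX6 below both controls (-0.90 and -0.46) and L3MBTL1 not above background on the EZH1-labelled array. Of 52 developmental genes repressed by Polycomb only 10 were detected, with medians of 0.039 and -0.16 (percentiles 42.2 and 9.38). HOXD3 was not above background on the EZH1-labelled array, and PAX6, an eye and brain regulator, differed by -0.013 from control 2 and was below background on control 1. G2 and mitosis genes had medians of -0.22 and 0.11 (percentiles 7.26 and 98.8), with 22 of 28 members above control 2, but the members that differed most went both ways: NDC80, a kinetochore protein, was 1.06 and 0.72 above the controls, CENPF, another, differed by -0.92 and -0.34, and CENPA, the centromeric histone, and BIRC5, survivin, differed by -1.59 and 0.014, and by -1.47 and 0.085. Interferon response genes gave 0.37 and -0.13 (percentiles 96.3 and 2.71), and ISG20, an antiviral exonuclease, differed by 2.85 and -0.13. No list had a member that passed the limma test in the EZH1 comparison, over all genes or adjusted over the list alone, and in the AML1-ETO comparison HLA-DPA1 was the exception described above.

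The number of lists outside the central 95% depended on the control. Of 38 lists, with 1.9 expected for random lists of unrelated genes, 13 lay outside for the AML1-ETO-labelled array against control 1 and 17 against control 2, and 10 and 3 for the EZH1-labelled array. The lists hold related genes and some share members, so 1.9 is not a chance level for them. Between the controls themselves 13 lists lay outside. Against both controls on the same side, 5 lists lay outside for the AML1-ETO-labelled array (granule, oxidative phosphorylation and endoplasmic reticulum chaperone genes higher, AML1-ETO activated and MHC class II genes lower) and 1 for the EZH1-labelled array.

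The knockdowns were also compared with each other. No gene was at least 2-fold above both controls, or at least 2-fold below both, on both knockdown arrays (0 and 0 genes, with 0.018 and 0.016 expected for independent lists). The direct limma contrast, EZH1 minus AML1-ETO, passed 0 of 13369 genes, with 198 at an unadjusted p under 0.05, and the mean of both knockdowns against control passed 0, with 12 at an unadjusted p under 0.05. Across genes, which are not independent replicates, the log2 differences from the shared control mean correlated at r = -0.32 (Spearman's rho -0.30, covariance -0.054). Simulated unchanged arrays, set against simulated controls that they shared, gave r = 0.34 and a covariance of 0.13. That simulation ignores the array pairs, and unchanged arrays simulated with the difference between the pairs gave r = -0.38 and a covariance of -0.073, so the negative value needs no opposite effects of the knockdowns. With each array set against its nearer control, which leaves no shared control, r was 0.027 (rho 0.034, covariance 0.0031), and with the controls crossed it was -0.77 (covariance -0.37). The change of the EZH1-labelled array from control 2, less that of the AML1-ETO-labelled array from control 1, was also taken for each list. This is a description with 1 array per knockdown. The median difference was -0.43 for granule genes and -0.31 for AML1-ETO repressed genes (percentiles 0.04 and 0.11). These lists share members such as RNASE2 and ELANE, so their values are not separate results. The median was -0.84 for hypoxia genes and 0.53 for MHC class II genes (percentiles 0 and 99.9). Other lists also lay outside the range of random lists. S phase genes gave 0.31, heat shock genes 0.18 and MYC target genes 0.10 (percentiles 100, 98.6 and 97.8). Glycolysis genes gave -0.23 and endoplasmic reticulum chaperone genes -0.26 (percentiles 0.52 and 1.13).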

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

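The tests of the difference between the array pairs and of the knockdowns themselves were chosen only after the list medians they rest on had been seen. Primary granule and neutrophil genes stood apart because they lay on opposite sides of the controls on the knockdown arrays: their median difference from the control mean was 0.27 on the AML1-ETO-labelled array and -0.37 on the EZH1-labelled array, and each direction held against both controls. Between the controls the list differed by a median of -0.33 (control 2 minus control 1, percentile 4.89), so the values against the control mean hold part of that difference. Against the nearer control the medians were 0.18 and -0.21, and the first lay at percentile 97.51, barely past the bound of 97.5. The difference between the knockdown arrays was not tested, since each knockdown has 1 array. The background correction, normalization or probe filter is not excluded as a source of part of the pattern. Both signs against the control mean were kept under 6 of 6 such settings, of which the mean of a gene's probes left both medians unchanged. With all probes the medians were 0.060 and -0.14, and the first lay inside the range of random lists (percentile 92.5). In the authors' values the median of the EZH1-labelled array was -0.21 (percentile 3.3), which also lay inside that range. The change of the EZH1-labelled array from control 2 less that of the AML1-ETO-labelled array from control 1 had a median of -0.43. Without CTSG and RNASE2, the members with the largest such difference, that median was -0.25 (percentile 4.09), so a few dominating members remain possible. The difference between the array pairs stays open too, because its test could not decide it. The test used the change from the nearer control, in which a shift common to an array pair cancels. That change differed by a median of -0.43 between the knockdowns (percentile 0.04 of random lists). The pattern itself fixes the sign of that value, so no conclusion is drawn from it. An effect of the knockdowns themselves also stays open as a hypothesis, as the EZH1-labelled array read -0.21 from control 2 (percentile 0.77) and cannot be told apart from any other difference of that single array.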

How the results depend on the processing

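The detection-floor and array-pair alternatives were chosen only after the data were seen; the others were planned. Counts of genes passing limma remained at 0 under all settings but 1: scaling to the 75th percentile passed 1 gene in the EZH1 comparison and 1 in the contrast of the knockdowns, LOC653321 in both (named after its values were seen; 3.92, adjusted p 0.0093, and 4.46, adjusted p 0.012, by limma); the cause was not tested. The count of 44 genes 2-fold from both controls in the AML1-ETO comparison was 5 without background correction, which compresses dim signals by construction, 5 in the authors' values, 13 with probes detected on all 4 arrays, 17 at the detection floor and 390 at 1.5-fold. The count of 21 in the EZH1 comparison was 5, 2, 11, 13 and 365 in the same order of settings. The correlation of -0.32 was -0.47 without background correction, -0.50 in the authors' values, -0.15 with all probes and -0.46 with probes detected on all 4 arrays; the cause was not tested. Outside the settings that leave out a control, 54 of 70 values of counts and the correlation stayed near the main value. Near meant equal or within 1.5-fold for a count, and the same sign within a fixed margin for the correlation. Of the list medians 102 of 120, and of the values of single genes 836 of 839, stayed as they were in direction and side of the threshold. The reversed ones were EZH1 in the EZH1 comparison (-0.049 with 75th percentile scaling, -0.020 in the authors' values), RUNX1 there (0.11 with the mean of probes) and the erythroid median there (-0.0092 with all probes); the cause was not tested. Medians inside the range of random lists that also changed sign were those of monocyte genes in the AML1-ETO comparison (-0.034) and G2 and Polycomb-repressed genes in the EZH1 comparison (0.0084 and 0.014) with 75th percentile scaling, and of PRC2 members there in the authors' values (-0.020). With each control left out in turn, the 2-fold counts were 257 to 1441 (AML1-ETO) and 49 to 2307 (EZH1), since 1 control is then enough to pass. Lists outside the central 95% numbered 13 to 17 and 3 to 10, and the correlation was 0.13 to 0.45, reversed. Unchanged arrays simulated against 1 shared control gave 0.50, so a shared control alone can make the correlation positive. That simulation ignores the array pairs, so the reversal cannot be read as a shared effect of the knockdowns or as its absence. With a control left out, the limma counts could not be fitted, as no residual degree of freedom remains. In the AML1-ETO comparison these 2 settings reversed the medians of hypoxia genes (-0.094 to 0.96) and S phase genes (-0.29 to 0.76), and ANKRD37 (-0.036 to 1.80), BNIP3 (-0.13 to 1.96), DDIT4 (-0.78 to 2.62), CCNE2 (-0.29 to 1.66), EZH1 (-0.57 to 0.32), ID1 (-0.47 to 2.21), RRM2 (-0.41 to 1.83) and RUNX1T1 (-0.47 to 0.18). In the EZH1 comparison they reversed the interferon median (-0.13 to 0.37), the G2 and Polycomb-repressed medians (-0.22 to 0.11 and -0.16 to 0.039), which were inside the range of random lists with both controls, BIRC5 (-1.47 to 0.085), CENPA (-1.59 to 0.014), EZH1 (-0.41 to 0.48), FOXC1 (-0.34 to 1.15), GBP2 (-0.017 to 2.74), ISG20 (-0.13 to 2.85), PAX6 (-0.013 to 0.96) and RUNX1T1 (-0.22 to 0.42). No paired analysis of a single knockdown was possible because each has 1 array. With both knockdowns as 1 group and the array pairs as a block, each knockdown array set with the control it resembles most, limma passed 0 genes, with 689 at an unadjusted p under 0.05 and 1 residual degree of freedom; these pairs come from the data and match the sample numbers, but no label states them. Signal over background limits EZH1, PAX6 and ANKRD37, which were below background on control 1, and the genes given as bounds.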

Other observations

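The tests of explanations for the control difference and for the hypoxia genes, and the set of small RNA genes, were chosen only after the results were seen; the test of bead error replaced an earlier one whose value was already known, and a test of the small RNA genes was dropped as a pattern after its value had been seen. Apart from the knockdowns, the arrays showed a broad split between control 1 and control 2. Amino acid response and ATF4 target genes were higher on control 2, with a median of 1.27 and 21 of 21 members higher, and interferon response genes had a median of 0.53 with 22 of 27 higher. Cholesterol synthesis genes had a median of -1.18 with 18 of 20 lower, heat shock genes -0.91 with 15 of 17 lower, and MYC target and ribosome biogenesis genes -0.79 with 26 of 28 lower. Among single genes, OSCAR, an immunoglobulin-like receptor, read 8.78 on control 2 and was below background on control 1, and PSMD1, a proteasome subunit, differed by -3.29. HSPE1, a mitochondrial chaperonin, differed by -2.53.

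Measuring error over beads is argued against as the source of this split, since 95.6% of the 2039 genes lay on the same side in the EZH1-labelled array minus the AML1-ETO-labelled array, which share no array with the controls. A signal-dependent bias of the normalization would move the lists like random lists matched on signal, with 1.9 of 38 expected outside the central 95%. It is argued against as the whole cause by 13 lists outside, on both sides. Dilution by ribosomal and small nuclear RNA would move mRNA lists alike, yet the amino acid response and cholesterol medians lay 2.45 apart, which argues against dilution as the whole cause. A difference in culture state or in RNA preparation between the array pairs may underlie the split and was not tested, as no label records either.

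Hypoxia and HIF target genes were high on the AML1-ETO-labelled array against control 1 but not against control 2. A mixture of the states of the controls that moves all lists in proportion to the hypoxia genes is argued against on the AML1-ETO-labelled array. The amino acid response median against control 1 was 0.022 where the controls differed by 1.27, and the cholesterol synthesis median was 0.083 where they differed by -1.18. Other lists moved part of the way toward control 2. S phase genes gave -0.29 where the controls differed by -0.96, MYC target genes -0.17 where they differed by -0.79, and heat shock genes -0.18 where they differed by -0.91. A partial shift of some genes is therefore not excluded. A low level on control 1 alone and the knockdown itself stay open and cannot be told apart: the median of -0.094 against control 2 (percentile 35.3) only restates the pattern, and the median of 0.96 against control 1 comes from 1 array.

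A set of 154 ribosomal, small nuclear, small nucleolar and related RNA genes had medians of 0.15 against control 1 and 0.16 against control 2 on the EZH1-labelled array (percentiles 94.8 and 100), the first inside the central 95% of random lists, and of -0.037 and -0.15 on the AML1-ETO-labelled array (percentiles 13.7 and 1.98), where the first was inside as well. Between the controls the median was 0.060 (percentile 59.6), but it hides large differences both ways. RNA28SN5, RNU1-3, a U1 spliceosomal RNA, SNORD3A, a U3 small nucleolar RNA, and RNVU1-18 were 3.48, 3.21, 3.09 and 2.89 higher on control 2, and SNORD14D differed by -1.90.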
